A study of Mus musculus with 2 samples.

How the data were processed

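Gene expression was measured with Affymetrix oligonucleotide arrays in liver RNA of mice that lack apolipoprotein E and were fed a high-fat diet. One array came from animals whose diet was enriched in the unsaponifiable fraction of olive oil (the sample titled orujo), and 1 array came from animals whose diet was enriched in olive oil. Per the labels, the targets were made by the manufacturer's standard procedure from about 8 µg of total RNA. The labels speak of animals in the plural for each array, but whether RNA of several animals was pooled is not given in the sources used here, and neither are sex, age, fasting state or time of day.

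The deposited values are probe set intensities on a linear scale with 1 decimal, as the authors summarised them. The software, its version and the detection calls are not given in the sources used here. The 2% trimmed mean over all 22690 probe sets was 100.05 on both arrays, so the deposited intensities had been scaled to a common trimmed mean of about 100, which fixes the average signal and leaves ratios between the arrays interpretable only relative to it. The median deposited intensity was 34.9 on the unsaponifiable fraction array and 36.4 on the olive oil array. The highest intensities were 8634.7 and 8102.7. An intensity of 0 was listed for 2 probe sets on the first array and for 1 on the second. An array has no read depth, and the number of arrays limits the precision.

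The 64 control probe sets were set apart. Each array was divided by its 2% trimmed mean over the other 22626 probe sets and brought to the mean of both, a change by a factor of 1.001 and 0.999. Values under the floor, which was the 50th percentile of both arrays' scaled intensities pooled (35.6), were raised to it, and log2 was taken. The floor stands in for detection calls: 11180 probe sets lay above it on the unsaponifiable fraction array and 11433 on the olive oil array. Of the 22626 probe sets, the platform annotation gave 1 gene symbol to 20380, several to 691 and none to 1555. The Entrez identifiers of 20351 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Probe sets with several symbols or none were named for no gene. No genome build is given for the probe sets, so no coordinates are printed. Each of the 12393 genes was represented by its probe set with the highest mean log2 value. A gene above the floor on both arrays is called measured, and its log2 ratio is the unsaponifiable fraction array minus the olive oil array. A gene above the floor on 1 array only has a lower bound, its signal against the floor. Genes below the floor on both arrays have no ratio.

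With 1 array per diet no test of the diets was possible, and no p-value is given. Genes are counted by size of ratio, with 2-fold as the limit. Each of 43 gene lists was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from measured genes matched on mean log2 value in 20 bins. A list stands apart if its median lay outside the central 95% of its random lists, and a list needed at least 5 measured members. This describes the 2 arrays and compares no animals. Different probe sets of a gene were compared as the only repeated measurement. They share RNA, labelling and hybridisation, so they show measurement noise and no variation between animals. The gene lists, the floor, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Apoe, the 12 highest and the 12 lowest measured log2 ratios, the 4 highest bounds in each direction, and from each list the highest and the lowest member and the 2 others with the largest absolute ratio. Genes named outside it are said to be. Some list members had no probe set with a single symbol here and were not analysed.

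The calculation was tested on simulated data for this comparison, with 12393 genes and the noise seen between probe sets. Of genes changed 4-fold, 100 of 100 were recovered, as were 100 of 100 changed 8-fold. Of 6617 unchanged measured genes, 7 passed 2-fold. The changed genes all lay more than 4-fold above the floor, and the simulated noise was the same at every intensity. Between real probe sets of a gene, the SD of the difference was 0.54 with the floor at the 25th percentile and 0.38 at the 75th. No single gene was planted with a change near the 2-fold limit. The simulation therefore shows recovery neither near the floor nor near that limit, and 7 of 6617 can understate false calls near the floor. A planted list of 25 genes shifted by 0.5 log2 units lay at percentile 100, and 12 of 200 unchanged lists stood apart. Alternatives were no scaling, centring on the median ratio, quantile normalization, loess with a span of 0.4, floors at the 25th and 75th percentile, log2(value + floor), the mean over a gene's probe sets, leaving out probe sets whose suffix marks sequence shared with other transcripts, limits of 1.5-fold and 3-fold, unmatched random lists and the mean of a list in place of its median. Leaving an array out was not possible. Acinar genes used for 1 test in the closing part were named before their values were looked at, and the condition of at least 5 measured genes was applied to that test only after its value was seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.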

Results

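Liver RNA of apolipoprotein E-deficient mice, a strain that develops high plasma cholesterol and atherosclerosis, was profiled on 2 arrays. The series asks how the type of olive oil in a high-fat diet relates to hepatic gene expression. One array represents a diet enriched in the unsaponifiable fraction, the minor oil components that are not fatty acid esters, and 1 array a diet enriched in olive oil. There were no replicates, so every ratio below compares these arrays and has no error between animals. Of 12393 genes, 6640 were measured on both arrays, 394 lay above the floor only on the unsaponifiable fraction array, 584 only on the olive oil array, and 4775 on neither.

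Apoe, the gene these mice lack, had a scaled signal of 99.7 on the unsaponifiable fraction array and 103 on the olive oil array, both above the floor of 35.6. Its single probe set gave a log2 ratio of −0.04. The position of this probe set relative to the deleted part is not known here, so the signal checks neither label.

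In this comparison of the 2 diets, genes of the hepatic acute phase response were higher on the unsaponifiable fraction array, led by Orm2 at 21.0-fold. The list of gluconeogenesis and fasting response genes was higher by its median as well (log2 ratio 0.43), though some of its members changed little. Cyp7a1 of bile acid synthesis was 4.20-fold higher. The list of glutathione metabolism and NRF2 targets (median −0.57), with Gstm3 5.05-fold lower, and the heat shock list (median −0.59), with Hspb1 5.51-fold lower, shifted the other way. Digestive enzyme genes of the pancreas were lowest, led by Ctrb1 at 13.1-fold.

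Across measured genes, log2 values correlated with a Pearson r of 0.96 (across genes, which are not replicates), and 97.7% of ratios were within 2-fold. At least 2-fold higher signal on the unsaponifiable fraction array was found for 90 measured genes, and at least 2-fold lower signal for 65. A further 14 genes were higher by a bound of at least 2-fold, and 14 were lower by such a bound. The SD of the log2 ratio over measured genes was 0.42. Where a gene had 2 measured probe sets (2057 genes), the difference between their log2 ratios had an SD of 0.43, which puts the measurement noise of a single probe set at 0.30. Of 41 such genes whose brighter probe set differed at least 2-fold, 34 went the same way in the second (82.9%, Wilson 95% interval 68.7% to 91.5%), and in 20 the second also passed 2-fold. With the floor at the 25th percentile the counts were 198 higher and 220 lower, and at the 75th percentile 51 higher and 27 lower.

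**Figure D1:**
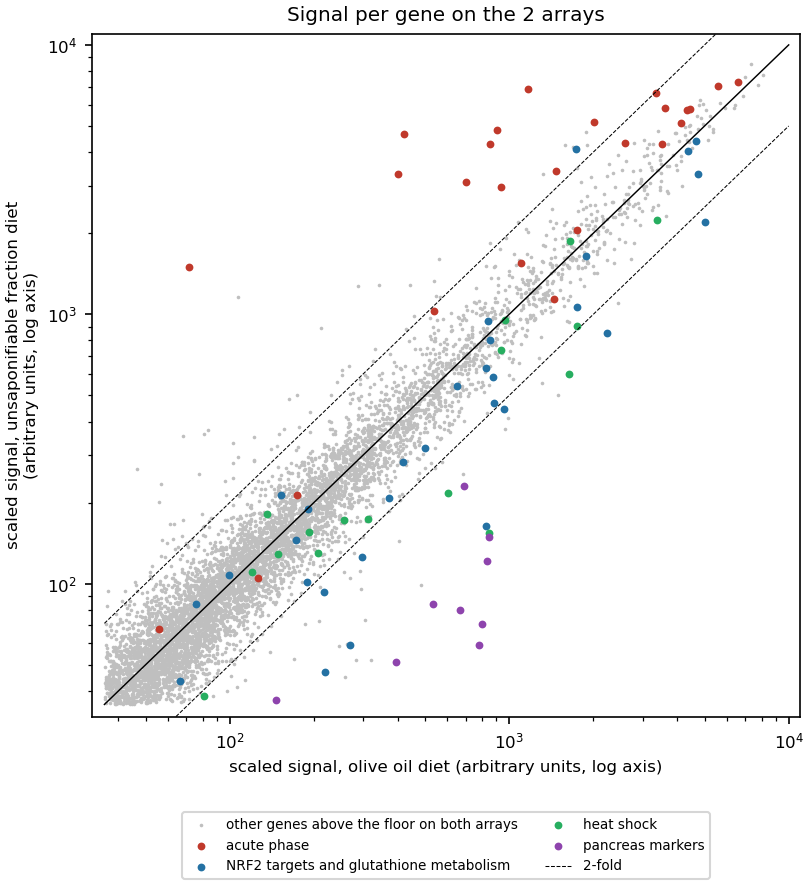
Scaled signal of each measured gene on the olive oil array (x axis) and the unsaponifiable fraction array (y axis), in arbitrary units on log axes, with 1 array per diet, genes of 4 lists in colour and dashed lines at 2-fold. The acute phase genes reach 21.0-fold above the diagonal (Orm2), and all 9 measured pancreas genes lie below the lower 2-fold line.

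Acute phase genes, which the liver makes in response to inflammation, held the highest measured ratio on the unsaponifiable fraction array. Nnmt, which is on no list, was 10.8-fold higher and ranked above several of them. Orm2, which encodes an orosomucoid, had a signal of 1498 against 71.4, a 21.0-fold higher value (log2 ratio 4.39). The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, were 11.1-fold and 5.86-fold higher. Lcn2, which encodes the siderophore-binding protein lipocalin 2, was 8.26-fold higher. Apcs, which encodes serum amyloid P component, was 5.36-fold higher. Saa2, which encodes a serum amyloid A, was 5.01-fold higher, from a probe set that can share signal with related transcripts. Orm3 was above the floor only on the unsaponifiable fraction array and at least 3.23-fold higher. Of 26 measured list members, 24 had positive ratios, 10 were at least 2-fold higher and 0 were at least 2-fold lower. The lowest member was Saa4, with a log2 ratio of −0.35. The list median of 0.72 lay above all 10000 random lists. On the same array the 5′ control probe set for 18S ribosomal RNA had a log2 ratio of 2.54 and its 3′ one 0.34. Lcn2 is also on the neutrophil list, of which 5 markers were above the floor only on this array and 0 only on the olive oil array, and whose median was 0.49 with the floor at the 25th percentile. Without the metallothioneins and Lcn2, an alternative added after the data were seen, the median of the acute phase list was 0.48.

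Complement and coagulation genes, of which C1qa, C1qb and C1qc are also on the macrophage list, showed a smaller shift in the same direction. Their median log2 ratio was 0.34 over 32 measured genes, at percentile 99.99 of the random lists, with 25 positive ratios and 2 genes at least 2-fold higher. These were Pros1, which encodes the anticoagulant protein S (3.23-fold), and C8b, a chain of complement component C8 (2.15-fold). The 18S 5′ control (2.54) and the pancreas marker median (−2.78) differed between the same arrays. C8a was 1.81-fold higher, and Klkb1, prekallikrein, was lowest at −0.35. Inflammatory cytokines and chemokines did not share this direction: 8 of 12 measured genes had negative ratios, and the median of −0.37 lay at percentile 0.21. Cxcl1 was lowest at −0.89 and Mif was at −0.55, while Ccl4 was at 0.91 and Vcam1 at 0.64. Vcam1's other probe sets had opposite signs, the lower at −0.73. With the mean in place of the median (−0.13) this list no longer stood apart, nor with the floor at the 75th percentile (−0.02) or with the Bonferroni limit. Interferon-stimulated genes had a median of 0.19 over 16 genes at percentile 96.9, inside the central 95%, though 4 alternatives put it outside, and ranged from Ifit1 at −0.62 to Oas1a at 0.54.

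Genes of gluconeogenesis and the fasting response were higher on the unsaponifiable fraction array. The median log2 ratio was 0.43 over 19 measured genes, above all 10000 random lists, with 16 positive ratios, 4 genes at least 2-fold higher and 0 at least 2-fold lower. Got1, a transaminase of amino acid and gluconeogenic metabolism, was 2.67-fold higher. Ppargc1a, which encodes the coactivator PGC-1α, was 2.53-fold higher, and its other measured probe set gave 0.85 on the log2 scale. Igfbp1, a fasting-induced binding protein of insulin-like growth factors, was 2.53-fold higher. Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, was above the floor only on this array and at least 2.70-fold higher. Gpt was the lowest member at −0.40. Other members, named outside the rule, moved little: Pck1 was at 0.16, Fgf21 at 0.11, Creb3l3 at −0.01 and Tat at −0.13, while G6pc was at 0.43. On the same array the 5′ control probe set for 18S ribosomal RNA was at 2.54, the pancreas markers had a median of −2.78, and the clock genes Nr1d1 and Nfil3 were at −2.13 and 1.34. Glycolysis and glucose uptake genes had a median of −0.11 over 12 genes at percentile 16.3, between Pygl at −0.63 and Gys2 at 0.72. Urea cycle and amino acid genes had a median of 0.14 over 27 genes at percentile 92.9, with Aass, of lysine breakdown, 2.47-fold higher, Got1 also a member, and Phgdh, of serine synthesis, 3.25-fold lower. Gpt and Phgdh were read from probe sets that can share signal with related transcripts.

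Cholesterol synthesis genes were higher on the unsaponifiable fraction array, with a median log2 ratio of 0.29 over 19 measured genes at percentile 99.9. Of these, 13 had positive ratios, 3 were at least 2-fold higher and 0 at least 2-fold lower. The list did not stand apart with the Bonferroni limit. The 18S 5′ control was at 2.54 and the pancreas marker median at −2.78 on this array. The 3 genes encode late enzymes of sterol synthesis: Tm7sf2 was 2.07-fold, Cyp51 2.04-fold and Dhcr7 2.03-fold higher. Mvd, mevalonate diphosphate decarboxylase, was the lowest at −0.92, while its second probe set gave 0.37. The bile acid list did not stand apart (median 0.11 over 20 genes, percentile 87.0), with 3 members at least 2-fold higher and 1 at least 2-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 4.20-fold higher, with log2 ratios of 2.07 and 2.18 in its 2 measured probe sets. Cyp7b1 was 2.16-fold and Cyp8b1, the sterol 12α-hydroxylase, 2.05-fold higher. Abcc3, a basolateral exporter of conjugated bile acids, was 2.36-fold lower. Cholesterol efflux and LXR target genes had a median of −0.03 over 13 genes at percentile 38.3, with Ces1g 2.32-fold lower and Lpcat3 at 0.57 on the log2 scale. Apolipoprotein and lipoprotein genes had a median of 0.16 over 24 genes at percentile 95.5. Their 2 members past 2-fold were Saa2 and Saa1, the latter 2.57-fold higher (2.58 on the log2 scale in its other probe set) and also on the acute phase list. Apom was 1.65-fold higher, with 0.14 on the log2 scale in its other probe set, and Lpl 1.59-fold lower.

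Fatty acid and triglyceride synthesis genes did not move as a group: their median was 0.11 over 18 genes, at percentile 87.7. Scd1, stearoyl-CoA desaturase, was 2.23-fold higher (1.89 on the log2 scale in its other probe set) and Lpin1, a phosphatidate phosphatase, 2.13-fold higher. Srebf1, the lipogenic transcription factor, was 1.68-fold lower. Fatty acid oxidation genes and PPARα targets had a median of −0.11 over 29 genes at percentile 3.23, inside the central 95%, with Angptl4 2.06-fold higher and Aldh3a2 1.71-fold lower. This list did stand apart under quantile normalization (−0.18), with the floor at the 75th percentile (−0.15) and without probe sets of shared sequence (−0.13). Lipid droplet and fatty acid uptake genes had a median of 0.19 over 17 genes at percentile 97.6, with 4 genes at least 2-fold higher. Fabp5, a fatty acid-binding protein, was 5.20-fold higher, Pnpla2, the adipose triglyceride lipase, 2.41-fold, and the droplet protein gene Plin5 2.16-fold. The call for this list ended under loess (0.15), under quantile normalization (0.15) and with the floor at the 75th percentile (0.16), with the Bonferroni limit, and when any 1 of 8 of its members was left out. The 18S 5′ control was at 2.54 here too, and the pancreas marker median at −2.78. Ketone body and mitochondrial respiration genes had a median of −0.06 over 23 genes at percentile 14.9, with values between Cox5b at −0.60 (−0.12 to 0.27 in its other probe sets) and Idh3a at 0.61.

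Genes of glutathione metabolism and targets of the oxidative stress regulator NRF2 were lower on the unsaponifiable fraction array. Of 30 measured genes, 25 had negative ratios, 8 were at least 2-fold lower and 1 was at least 2-fold higher, and the median of −0.57 lay below all 10000 random lists. Without glutathione transferases, an alternative added after the data were seen, the median over 17 genes was −0.25 at percentile 0.41, with 2 genes at least 2-fold lower, and it did not stand apart with the Bonferroni limit over the lists. Pancreas markers were also lower on this array, with a median of −2.78, and the 5′ control probe set for 18S ribosomal RNA had a log2 ratio of 2.54. The glutathione transferase genes Gstm3, Gsta4 and Gsta2 were 5.05-fold, 4.64-fold and 4.53-fold lower. Gstm3's second probe set gave −2.26. The single gene above 2-fold was Sod1, superoxide dismutase 1, at 1.24, but its other probe set gave −0.50. AhR targets showed no common direction (median 0.17 over 5 genes, percentile 83.3), with Nqo1 at −0.61 and Tiparp at 0.58. The xenobiotic list had a median of −0.13 over 18 genes at percentile 3.39. It held Cyp2b10, a cytochrome P450 induced through the receptor CAR, which was 4.43-fold higher with its other probe sets between 1.74 and 2.23, as well as Abcc3, which was lower. Cyp17a1, a steroid hydroxylase, was above the floor only on the unsaponifiable fraction array and at least 4.10-fold higher.

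Heat shock genes, which encode chaperones, were lower on the unsaponifiable fraction array too. The median was −0.59 over 16 genes, below all random lists, with 14 negative ratios and 4 genes at least 2-fold lower. Hspb1, a small heat shock protein gene, was 5.51-fold lower, with −2.68 in its second probe set. Hsph1 was 2.77-fold and Hspa1b 2.73-fold lower, and their other probe sets gave −1.60, and −1.52 to −1.29. Hspa4 had the highest ratio at 0.42, with −0.68 in another probe set. Proteasome genes shifted slightly the same way, with 21 of 26 ratios negative, 0 past 2-fold and a median of −0.22 at percentile 0.14. Psmd14 was lowest at −0.53, and the list did not stand apart with the Bonferroni limit. Unfolded protein response genes had a median of −0.07 over 26 genes at percentile 17.7. Pdia4, an endoplasmic reticulum chaperone, was 2.68-fold lower, but its second probe set gave −0.19. On the same array the pancreatic transcripts had a median of −2.78, and the 5′ control probe set for 18S ribosomal RNA had a log2 ratio of 2.54.

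Transcripts of the exocrine pancreas gave the lowest ratios of all. Of 9 measured members of the pancreas list, 9 were at least 2-fold lower on the unsaponifiable fraction array, and the median of −2.78 lay below all random lists. Ctrb1, which encodes chymotrypsinogen, had a signal of 59.3 against 777 on the olive oil array, a 13.1-fold lower value. The carboxypeptidase genes Cpa1 and Cpb1 were 11.3-fold and 6.37-fold lower, the elastase genes Cela2a and Cela3b 8.35-fold and 6.89-fold, the colipase gene Clps 7.65-fold, and the trypsinogen gene Prss2 5.70-fold. Pnliprp1 was above the floor only on the olive oil array and at least 6.91-fold higher there. Outside the list, Dmbt1, Ctrl and Cel were 6.12-fold, 5.74-fold and 5.43-fold lower, and Sycn was lower by a bound of 6.80-fold. With pancreatic and acinar genes left out, an alternative added after the data were seen, 49 of the 65 lower genes remained and all 90 higher genes. Those left out were the pancreas list, acinar genes picked before their values were seen, and 9 acinar genes seen among the largest ratios. The 49 can therefore still hold pancreatic transcripts.

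Markers of the cell types of the liver with at least 5 measured members gave medians inside the range of their random lists. Hepatocyte markers had a median of 0.04 over 17 genes at percentile 50.7, between Cebpa at −0.39 and Arg1 at 0.49. Macrophage and Kupffer cell markers had a median of 0.05 over 22 genes at percentile 79.4, with Ptprc at −0.99 and Laptm5 at 0.54. Endothelial markers were at 0.06 over 14 genes (percentile 76.2; Kdr −0.30, Plvap 0.36). Stellate cell and matrix genes were at 0.07 over 22 genes (percentile 85.9), with Col5a2 2.20-fold higher and Acta2 1.60-fold lower. MHC class II and antigen presentation genes were at 0.04 over 9 genes (percentile 63.8, H2-Aa −0.14 with 0.18 in its other probe set, H2-D1 0.41). Laptm5 and H2-Aa were read from probe sets that can share signal with related transcripts. Neutrophil markers were at −0.07 over 6 genes (percentile 45.8), from Mmp9, 2-fold lower, to Lcn2, 8.26-fold higher, but 5 others were above the floor only on the unsaponifiable fraction array and 0 only on the olive oil array. With the floor at the 25th percentile, 12 neutrophil markers were measured and their median of 0.49 stood apart. Cholangiocyte markers had too few measured members for a median with the main floor. With the floor at the 25th percentile, 5 were measured and their median of −0.58, lower on the unsaponifiable fraction array, stood apart.

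**Figure D2:**
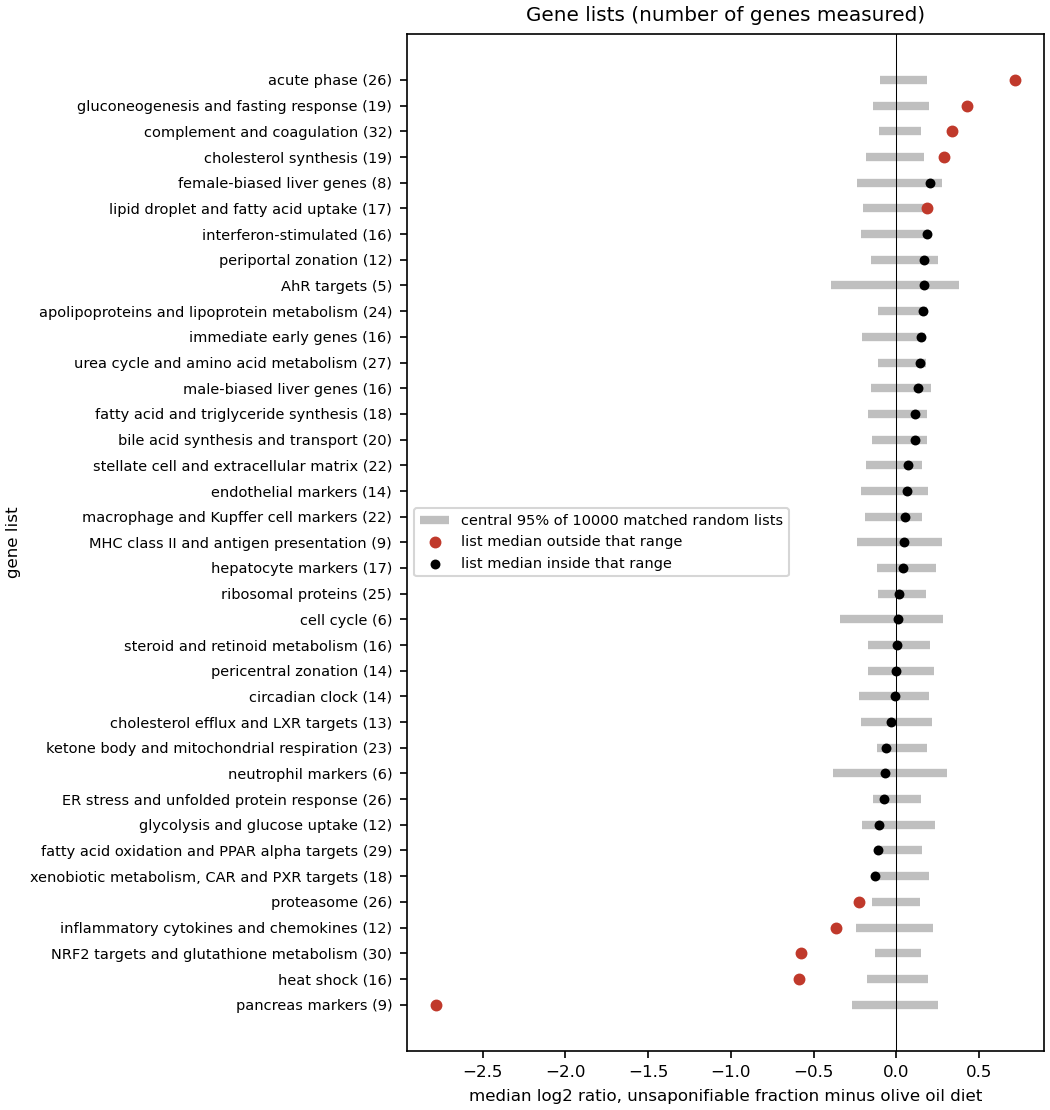
Median log2 ratio (x axis, unsaponifiable fraction minus olive oil) of the 37 gene lists (y axis, number of measured genes in parentheses) with at least 5 measured members, 1 array per diet. Grey bars are the central 95% of 10000 matched random lists, and red points are the 10 medians outside it, from −2.78 for pancreas markers to 0.72 for acute phase genes.

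In all, 10 of 37 lists stood apart, 5 higher and 5 lower, where 1.85 would be expected if each list were a random draw of genes. Overlap between lists changes the spread of that count and not its expected value. Members of a list can vary together between any 2 samples, which random draws of genes do not copy. More lists than 1.85 can therefore stand apart without an effect of the diet, and this holds for the stricter limit below as well. With a Bonferroni limit over the lists, added after the data were seen, 6 stood apart: acute phase, complement and coagulation, and gluconeogenesis and fasting response were higher, and glutathione metabolism with NRF2 targets, heat shock and pancreas markers were lower.

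**Figure D3:**
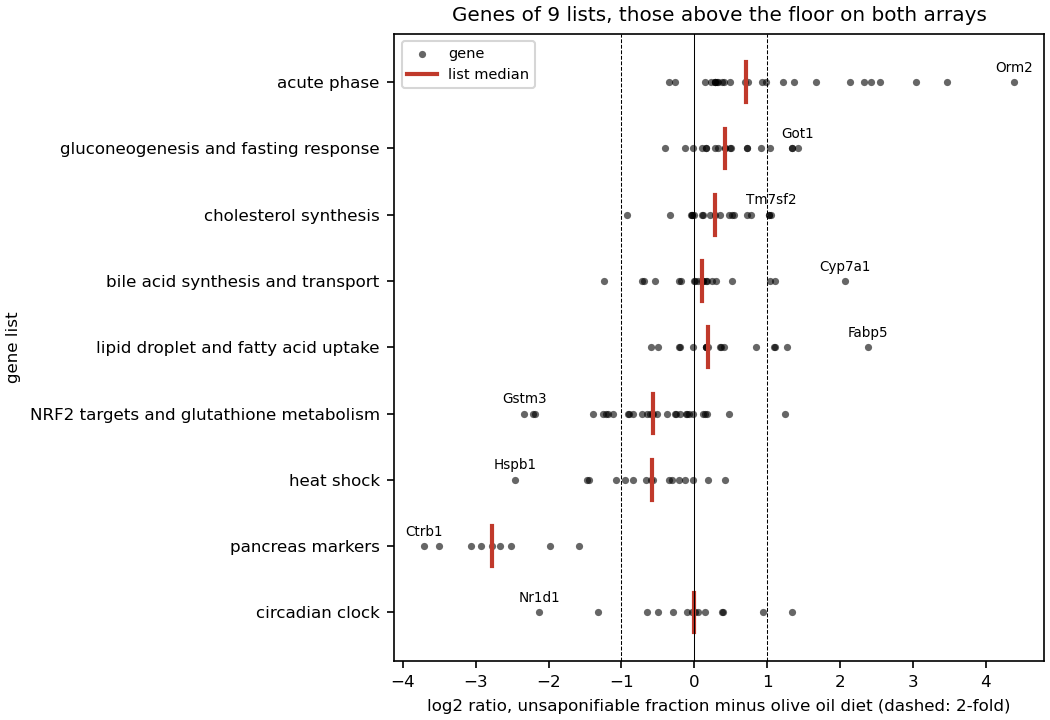
Log2 ratio (x axis, unsaponifiable fraction minus olive oil, dashed lines at 2-fold) of each measured gene in 9 gene lists (y axis), 1 array per diet, with a red line at each list median and the gene with the largest absolute ratio named. The circadian clock list has a median of −0.01 with members from −2.13 (Nr1d1) to 1.34 (Nfil3).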

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

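All tests in this part were chosen after the results were seen, except that of acinar genes outside the pancreas list, which were picked before their values were looked at.

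Control probe sets for 18S ribosomal RNA differed between the arrays: the 5′ probe set had a signal of 2297 on the unsaponifiable fraction array against 395 (log2 ratio 2.54), and the middle one 1233 against 221 (log2 ratio 2.48), while the 3′ probe set was at 0.34. The 18 spiked control probe sets above the floor on both arrays had a median log2 ratio of 0.31, from −0.03 to 0.74. Among probe sets with no gene symbol that were above the floor on both arrays, 18 were at least 2-fold higher on the unsaponifiable fraction array and 4 lower. Among those with several symbols and above the floor on both arrays, 0 were at least 2-fold higher and 8 lower, among them, named after their values were seen, probe sets for pancreatic amylases (6.04-fold lower) and for Cela3a and Cela3b (10.9-fold lower).

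The first pattern is the higher level of pancreatic enzyme transcripts on the olive oil array, and a scaling or intensity trend is argued against by the median of −2.78 that the pancreas list had after loess. A candidate explanation is that pancreatic tissue, which lies next to the liver, was carried into the olive oil sample. Its test was the median log2 ratio of acinar genes picked before their values were seen, with a median above −0.5 set beforehand as counting against it; the value was 0.56, which met that bound and was at first read as excluding pancreatic tissue. That bound gave no minimum number of genes, and of 12 such genes on the array only Rbpjl was measured on both (53.5 against 36.2, near the floor of 35.6), 3 lay above the floor only on the olive oil array and 8 on neither, so a minimum of 5 genes was added after the value was seen and the test was then taken to decide nothing. Pancreatic tissue and an effect of the diet on transcripts of liver cells cannot be told apart with 1 array per diet.

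The second pattern is the higher level of acute phase and fasting transcripts on the unsaponifiable fraction array. More macrophages as the source of the acute phase transcripts are argued against. The macrophage median of 0.05 lay 0.664 below the acute phase median, more than the SD over the macrophage markers (0.378). For the fasting transcripts the gap of 0.374 fell just short of that SD, so by this rule macrophages stay open as their source. The SD is a spread over genes and not the error of a median, so a gap just under it decides little. Of 22 measured macrophage markers, 12 had positive and 10 negative ratios. More neutrophils stay open: the neutrophil median was −0.07 with the main floor and 0.49 with the floor at the 25th percentile. The latter rests in part on signals below the main floor. A different time of day stays open too, since the difference of 1.34 between genes that peak with Arntl and those that peak with Nr1d1 rests on the genes that prompted the test, and without these 4 the difference of 0.56 had only 1 gene on the Arntl side. Illness or food intake of single animals cannot be told apart from the diet with 1 array per diet, and the diet itself stays open as untested.

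The third pattern is the lower level of glutathione and heat shock transcripts on the unsaponifiable fraction array. Signal shared between glutathione transferase paralogs is argued against as the whole cause, since the list without them still had a median of −0.25, below the central 95% of its random lists (lower limit −0.17). A scaling or intensity trend is argued against by the random lists matched on signal. Their central 95% reached down only to −0.13 for the glutathione list and −0.18 for the heat shock list. After loess the higher of the 2 medians was −0.57. Since loess moved 0 of 37 list medians by the SD of their random lists or more, it adds no separate evidence. A large loss of 5′ signal in the unsaponifiable fraction sample is argued against, since it would put the 3′ ratio above the 5′ ratio. The 3′ minus 5′ difference was −0.0325 for Gapdh, −0.25 for beta-actin and −0.24 for pyruvate carboxylase. It was −2.20 for 18S ribosomal RNA, whose weak 5′ signal was on the other array. Apart from 18S, these differences lie within the SD of 0.43 between probe sets of a gene, so a small loss is not excluded. The diet and differences between animals stay open, as untested.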

How the results depend on the processing

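Alternatives added after the data were seen were the Bonferroni limit, leaving out pancreatic and acinar genes, leaving out metallothioneins and Lcn2, leaving out glutathione transferases, and leaving out single list members. No scaling, median-centring, quantile normalization, loess, the mean over probe sets and leaving out probe sets with shared sequence kept each count of genes within 1.5 times, and the median ratio of all measured genes stayed between −0.03 and 0.00 under every scaling and floor. The measured counts (90 higher, 65 lower) became 198 and 220 with the floor at the 25th percentile, 51 and 27 at the 75th, 56 and 40 with log2(value + floor), 370 and 369 at 1.5-fold, and 20 and 22 at 3-fold. The counts of bounds (14 higher, 14 lower) became 87 and 146 with the floor at the 25th percentile, 9 and 22 at the 75th, 60 and 89 at 1.5-fold, and 2 and 5 at 3-fold; log2(value + floor) gives no bounds. The number of lists standing apart was 10, between 8 and 13 under the alternatives set before the data were examined, and 6 with the Bonferroni limit. Of the genes named in the text, no single gene at least 2-fold different and no list standing apart changed sign under any alternative that gave it a value. Sizes did change. With log2(value + floor), 38 of 174 ratios of genes under the naming rule moved by at least 0.30, the noise of a single probe set. The mean in place of the median moved 12 of 37 list values by at least the SD of their random lists, and quantile normalization 8 of 37. Loess moved 0 of either. Under alternatives set beforehand the lipid droplet list and the cytokine list lost their call, and the Bonferroni limit ended those of the cholesterol synthesis and proteasome lists too. The pancreas list had only 3 measured members with the floor at the 75th percentile, too few for a median. Lists that stood apart only under some alternatives were those of fatty acid oxidation, interferon-stimulated, immediate early, neutrophil, cholangiocyte, female-biased, apolipoprotein, and urea cycle genes. Leaving out 1 member ended the call of the lipid droplet list for 8 of its members and of no other list. The SD between probe sets was 0.43, and 0.38 to 0.54 under the alternatives. Signals near the floor limit what can be said of low genes, and leaving out an array was not possible.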

Other observations

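In this part the grouping of clock genes by the time of their peak was chosen after the results were seen.

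Several genes with large ratios fall outside the lists. On the unsaponifiable fraction array, Nnmt, nicotinamide N-methyltransferase, was 10.8-fold higher, Lepr, the leptin receptor gene, 5.76-fold, Prg4, which encodes the secreted proteoglycan lubricin, 4.46-fold, and Ddit4, a stress-induced inhibitor of mTOR signalling, 4.45-fold. The uncharacterised gene 1700017B05Rik was above the floor only on this array and at least 2.79-fold higher. On the olive oil array, Smpd2, a sphingomyelinase gene, was at least 4.93-fold higher and Lsm7 at least 3.21-fold higher. A probe set annotated to both Snurf and Snrpn, chosen after its value was seen, was 6.26-fold lower on the unsaponifiable fraction array.

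The circadian clock list held opposite movements that its median of −0.01 over 14 genes (percentile 53.4) hides. Nr1d1, which encodes the repressor REV-ERBα, was 4.38-fold lower and Dbp, a clock output transcription factor, 2.50-fold lower, with log2 ratios of −1.32 and −1.33 in its 2 measured probe sets. Nfil3, which opposes Dbp, was 2.53-fold higher and Arntl, which encodes BMAL1, 1.91-fold higher. Of 8 measured genes that peak with Nr1d1, 2 had positive ratios, Tef (0.15) and Usp2 (0.38), both named after their values were seen.

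Zonation lists did not stand apart: periportal genes had a median of 0.17 over 12 genes (percentile 89.5; Asl 0.54, Cyp2f2 −0.15) and pericentral genes −0.00 over 14 (percentile 44.4), from Gstm3 at −2.34 to Cyp7a1 at 2.07, with the glutamine synthetase gene Glul at 0.58 (0.05 in its other probe set). Male-biased liver genes had a median of 0.13 over 16 genes (percentile 88.7), with Lifr 2.24-fold higher (0.58 on the log2 scale in its other probe set) and Hsd3b5, a male-predominant steroid dehydrogenase gene, 2.18-fold lower. Female-biased genes had a median of 0.20 over 8 genes (percentile 92.9), from Aldh1a1 at −0.31 to Cyp2b10 at 2.15. The Y-linked genes Eif2s3y and Uty were above the floor of 35.6 on both arrays at −0.22 and −0.34. Their signals were low, at 46.4 against 54.2 for Eif2s3y and 57.7 against 72.8 for Uty. Named after their values were seen, Y-linked Kdm5d was above the floor only on the unsaponifiable fraction array (44.3 against 20.7) and Xist only on the olive oil array (47.5 against 32.2). Signals this near the floor were not read as a difference in sex. A probe set annotated to both Cyp3a41a and Cyp3a41b, the first of them on the female-biased list, was named after its value was seen. It was above the floor only on the olive oil array (147 against 19.1) and at least 4.11-fold higher there. Of the 8 measured female-biased genes, 5 had positive ratios, the other direction. Whether the samples differed in sex was not tested. Steroid and retinoid genes had a median of 0.00 over 16 genes (percentile 50.5), with Cyp26a1, which degrades retinoic acid, 2.11-fold higher. Immediate early genes had a median of 0.15 over 16 genes (percentile 95.8; Gadd45g 1.32, Fos −0.52). Ribosomal protein genes had a median of 0.02 over 25 genes (percentile 49.1; Rps27 0.58, Rpl22 −0.64) and cell cycle genes 0.01 over 6 (percentile 60.4; Rrm1 0.38, Ccnd1 −0.42).

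The remaining lists had fewer than 5 measured members. T, NK and B cell markers had 2 (Il2rb −0.74, Ighm 0.27), erythroid and blood markers 4 (Pf4 −0.08 to Hbb-b2 0.98), cholangiocyte markers 2 (Anxa2 −0.58, Tspan8 0.11), adipocyte markers 4 (Retn −0.25 to Fabp4 0.84), muscle and kidney markers 1 (Kap −0.15) and sex chromosome genes 2.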
